A study of Mus musculus with 4 samples.

How the data were processed

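Cortical cells of 4 mouse embryos (C57BL/6, E16.5) were profiled by droplet single-cell RNA sequencing, 2 mice labelled HET, which is not defined there, and 2 labelled COP1 KO. Per the labels' protocols, the cortex was dissociated with papain, libraries were made with the 10x Chromium 3′ kit v2, which reads the 3′ ends of transcripts, and each library was sequenced on its own lane of a HiSeq4000. Per the submitters' processing notes, the tool named is the aligner GSNAP and the genome build is GRCm38 (mm10). The counter, the gene annotation, the collapsing of molecular identifiers and the rule that called cell barcodes are not given in the sources used here. The deposited values are whole-number counts per gene and cell barcode, not normalized, with 1 table per library.

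Each table had 36528 gene rows. Of these, 3065 carried only a number in place of a symbol and held 1.69% of the counts. They could not be matched to a symbol, so genes among them cannot be named. Of 33463 named genes, 30956 matched a symbol or synonym in the RefSeq annotation of GRCm38.p6. Some genes held identical counts in every barcode under several names, in 269 groups, and 367 copies holding 1.34% of the counts were removed so that no count entered more than once. Coordinates are from that RefSeq annotation. Genes that share reads with near-identical copies, such as ribosomal protein genes and their pseudogenes, histone genes, hemoglobin genes and Rnf121, are uncertain because the sources do not say how such reads were assigned.

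The tables held 19237 barcodes. Cells with fewer than 500 genes (222 barcodes, whose counts were 93.2% to 94.6% hemoglobin by the median of each library) and 1 cell with over 10% mitochondrial counts were removed. Scrublet's automatic threshold marked 16 barcodes (0.08%), too few to be credible, so a doublet score of 0.25 was set after seeing the data and removed 226 (1.19%). This left 18788 cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1.0 over all libraries without integration (scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Python 3.11.15). Clusters were called after a cell type, as "-like", from marker genes written beforehand. The naming thresholds were set after seeing the data: a mean marker score of at least 0.5, a margin of 0.3 over the next type, and 3 markers detected in 10% of cells. Clusters that missed them stayed unnamed.

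The library, which stands for 1 mouse, was the replicate. Raw counts were summed over all kept cells of a library, and over the cells of each class with at least 20 cells in every library. Sums were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM normalization, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of an edgeR value was taken as its absolute log2 change over the square root of F, which is unreliable for very small changes. Class shares were tested with the same edgeR test on cell counts, with the number of kept cells as library size. Whether an effect differed between radial-glia-like and excitatory-neuron-like cells was tested as a class-by-genotype term, with the library as a block. An exact permutation of 2 libraries against 2 cannot give a two-sided p below 0.333, so all p-values rest on spread that edgeR pools over genes or classes. The labels call the samples mice but give no litter, batch or replicate number.

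Gene lists, 33 in all, were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists, and within classes over all lists and classes. Each test was repeated with an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance. With an estimated correlation none of the list calls held, in the whole library (adjusted p = 0.733 for each list called) or within classes (adjusted p of 0.805 or more). That test rests on the residual spread of 4 libraries, so hardly any list could pass, and it decides neither for nor against a list. The test with the preset correlation takes its error from the spread over genes, not between mice. Its p-values thus do not measure variation between animals, however small they are. With fry, no list called in the whole library held, and most called within classes did not. A fry p is printed only where a list passed. The lists of COP1 substrates, ERK and ETS targets, AP-1 targets, the oligodendrocyte lineage and the astrocyte lineage were written with general knowledge of the published study of this gene in mouse brain, so they are not independent evidence of direction.

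The tests, markers, lists and the rule for named genes were fixed before the data were examined. The rule took the COP1 ligase partners and substrates that passed the filter, and, among genes past the threshold with a mean of at least 20 CPM (counts scaled to a common library size) in 1 group and non-overlapping libraries, the 10 largest folds each way for the whole library. It took 6 each way for each of the 3 largest classes and 3 each way for each other class. It also took up to 4 members with the smallest p of each list described, and 6 glial genes. Where fewer than 6 genes passed, those with the smallest p were added and are given as values. Sex-linked, unnamed predicted, hemoglobin and mitochondrial genes were left out of the ranking. Genes outside the rule are marked as chosen after their values were seen.

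For shares of cells with a molecule of a gene, each cell was thinned to 2000 counts. This left out 139 cells of COP1 KO replicate 1, 22 of COP1 KO replicate 2 and 0 HET cells. Shares in single libraries carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Alternatives were DESeq2 1.42.0, other normalizations and filters, other cell filters and clusterings, and each library left out in turn. When a library is left out, the lone library of its genotype is assumed to vary like the other group.

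The tests were checked on simulated counts drawn around the real means, with 200 changed genes picked among genes that were not of low counts. For the whole library (16746 genes), edgeR recovered 20.9% of genes changed 1.5-fold, 68.7% at 2-fold and 95.5% at 4-fold, and 18 of its 141 calls were unchanged genes. For radial-glia-like sums (11222 genes) the recoveries were 29.9%, 65.7% and 95.5%, with 14 of 141 calls unchanged. For excitatory-neuron-like sums (14464 genes) they were 55.2%, 70.1% and 97%, with 22 of 170 calls unchanged. For the class-by-genotype term (14683 genes) they were 40.3%, 88.1% and 97%, with 4 of 154 calls unchanged. Except for that term, the shares of unchanged genes among the calls lay above the 0.05 aimed at. Each library was drawn independently, and no library was made to stand apart as COP1 KO replicate 1 does. These recoveries thus do not show the power of the tests on the real counts. The share test found a class set 3-fold higher in 98 of 100 simulated sets. Those sets used assumed class shares and an assumed spread between libraries, not values fitted to these data. They do not show the power of the share test at the spread seen here. Plots were drawn with matplotlib 3.10.9.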

Results

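The data compare single cortical cells of HET mice with those of COP1 KO mice at E16.5, with 2 libraries of each. COP1 is the substrate-recognition part of a ubiquitin ligase that marks transcription factors such as c-JUN and the ETS factors ETV1, ETV4 and ETV5 for destruction. The deposited totals were 28327090 and 28071382 counts for the HET libraries and 28049007 and 28988265 for the COP1 KO libraries. After filtering, 4548 and 4316 HET cells and 5195 and 4729 COP1 KO cells remained, with median depths of 5174 and 5476 counts per cell in HET and 4504 and 5134 in COP1 KO. The labels do not say what HET stands for, and their titles call the COP1 KO samples CKO without naming a driver. Each genotype had 1 female and 1 male library by Xist and Y-linked counts. Counts of libraries of the same genotype differed by more than sampling noise, with chi-square values per degree of freedom of 12.86 for the HET pair and 23.08 for the COP1 KO pair. Across genotypes the values ranged from 12.14 (HET replicate 2 with COP1 KO replicate 2) to 29.66 (HET replicate 1 with COP1 KO replicate 1). Libraries of the same genotype were thus not always more alike.

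COP1 KO replicate 1 stood apart from the other 3 libraries. Of 7519 genes, 327 lay over 0.5 log2 units from the mean of the other libraries, against 117 and 71 for HET replicates 1 and 2 and 65 for COP1 KO replicate 2. The first principal component of the 4 whole-library sums held 57.5% of their variance. Its loadings were 0.846 for COP1 KO replicate 1, −0.287 for COP1 KO replicate 2, and −0.126 and −0.432 for HET replicates 1 and 2. Counts of changed genes are also given with each library left out, as was planned.

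The targeted gene, listed under its older symbol Rfwd2 (GRCm38.p6 chromosome 1, 159232156 to 159354872), did not differ past the threshold. It had 31.8 and 38.8 CPM in the HET libraries and 31.4 and 29.6 CPM in the COP1 KO libraries (log2 change −0.21, SE 0.113, edgeR adjusted p = 0.539). Its log2 change was −0.43 in radial-glia-like sums, −0.77 in intermediate-progenitor-like sums and −0.85 in ganglionic-eminence-progenitor-like sums, with edgeR adjusted p of 0.467, 0.278 and 0.412. The deleted part is not given in the labels, and 3′ tags outside it would still be counted, so these values do not check the genotype labels.

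The 18788 cells formed 33 clusters. Excitatory-neuron-like cells were the largest class with 10206 cells, followed by cortical-interneuron-like (1927), striatal-projection-neuron-like (1710), radial-glia-like (1205), ganglionic-eminence-progenitor-like (842), intermediate-progenitor-like (783), oligodendrocyte-precursor-like (325) and Cajal-Retzius-like cells (247). Fibroblast-, microglia-, endothelial-, mural- and erythroid-like cells made up smaller classes. Unnamed clusters held 6.18% and 6.79% of HET cells and 5.93% and 7.36% of COP1 KO cells.

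The first question was whether the genotypes differed in the share of each cell class. Oligodendrocyte-precursor-like cells were 3.26-fold more frequent in COP1 KO. The class was named from the mean score of a marker list that holds Olig1, Olig2, Pdgfra and Sox10, which not every cell of it expressed. They made up 0.791% ± 0.061 of HET cells (SD, n = 2) and 2.59% ± 0.528 of COP1 KO cells (SD, n = 2). By library the shares were 0.748% (exact 95% interval 0.518 to 1.04) and 0.834% (0.585 to 1.15) in HET, and 2.21% (1.83 to 2.65) and 2.96% (2.50 to 3.48) in COP1 KO. The log2 ratio was 1.70 (SE 0.223, edgeR quasi-likelihood adjusted p = 3.53e-07 over 14 classes), higher in both COP1 KO libraries than in either HET library. When cells were clustered without the 377 genes called within any class, the shares were 0.791% and 2.30%, with a log2 ratio of 1.54 (SE 0.233, edgeR adjusted p = 4.01e-06). With HET replicate 1 or HET replicate 2 left out, the log2 ratio was 1.63 or 1.78 and the edgeR adjusted p was 0.306 or 0.125, past the threshold in neither case. Without COP1 KO replicate 1 it was 1.90 (edgeR adjusted p = 1.94e-05).

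None of the other 13 classes, unnamed cells included, passed the edgeR test, and at an unadjusted p under 0.05 the count was also 0. Radial-glia-like cells were 6.19% ± 0.516 of HET and 6.61% ± 0.202 of COP1 KO cells (SD, n = 2 each; log2 ratio 0.10, SE 0.15). Ganglionic-eminence-progenitor-like cells had a log2 ratio of 0.30 and cortical-interneuron-like cells of −0.24, both with an edgeR adjusted p of 0.449. Excitatory-neuron-like cells were 54.9% ± 2.28 of HET and 53.7% ± 2.39 of COP1 KO cells (SD, n = 2 each). Microglia-like cells numbered 34 in HET and 52 in COP1 KO (log2 ratio 0.45, edgeR adjusted p = 0.714).

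**Figure D1:**
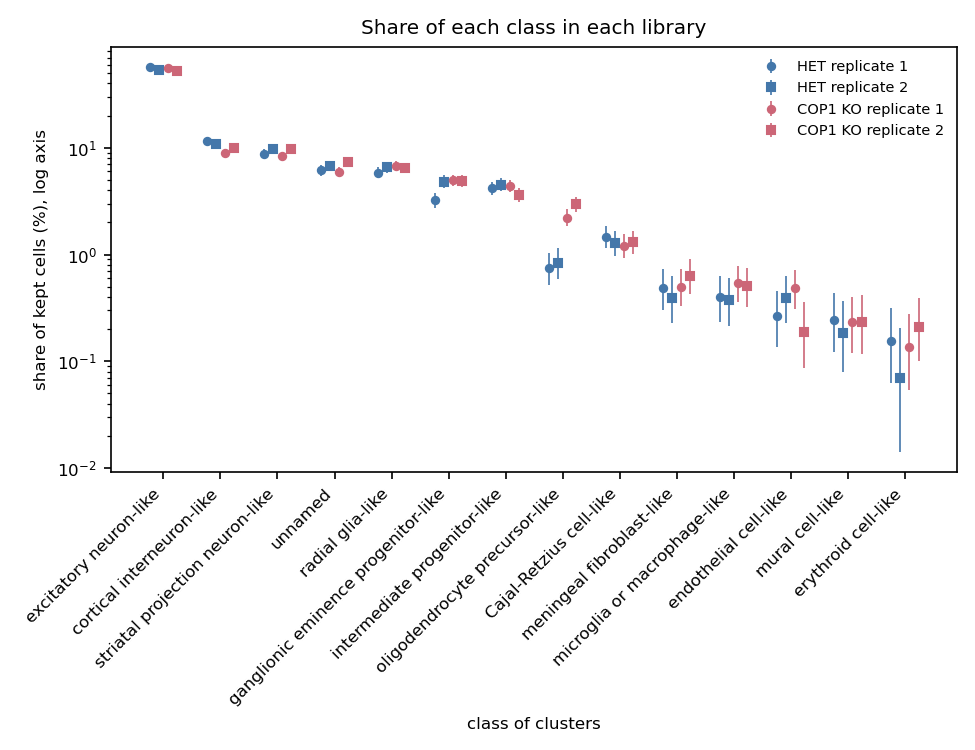
Share of kept cells in each class (y axis, percent, log scale) for each of the 4 libraries (points) with exact 95% intervals (bars). Oligodendrocyte-precursor-like cells lie at 0.748% and 0.834% in the HET libraries and at 2.21% and 2.96% in the COP1 KO libraries.

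Shares of cells with a molecule of a glial gene do not depend on clusters. After thinning to 2000 counts, cells with Olig1, a transcription factor of the oligodendrocyte lineage, were 0.902% ± 0.03 of HET and 2.82% ± 0.636 of COP1 KO cells (SD, n = 2 each), a ratio of 3.13. Its background in excitatory-neuron-like cells, which should lack it, was 0.143% and 0.373%, at median depths of 5926 and 6290 counts in HET and 5117 and 5975 in COP1 KO. Olig2, its close relative, was in 1.16% and 2.93% of cells (ratio 2.54; background 0.041% and 0.304%). Gfap, an intermediate filament gene of astrocytes, was in 0.296% and 1.58% (ratio 5.34; background 0.022% and 0.078%), and within radial-glia-like cells in 1.99% ± 0.682 and 13.1% ± 3.18 (SD, n = 2 each). Sox10, a transcription factor of committed oligodendrocyte precursors, was in 0.226% and 0.392% (ratio 1.73; background 0% and 0.018%). Pdgfra, a growth factor receptor of these precursors, was in 0.629% and 0.890% (ratio 1.42; background 0.058% and 0.192%), and the libraries of the genotypes overlapped. Vim, an intermediate filament gene of progenitors, was in 19.8% and 25.8% (ratio 1.31; 9.68% and 12% of excitatory-neuron-like cells). Without thinning, the ratios were 3.14 for Olig1, 2.44 for Olig2, 4.16 for Gfap, 1.98 for Sox10, 1.71 for Pdgfra and 1.17 for Vim.

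Summed over whole libraries, Lgals1 was the gene that passed the test. It encodes galectin-1, a carbohydrate-binding protein (GRCm38.p6 chromosome 15, 78926725 to 78930465), and rose from 58.1 ± 2.41 to 184.5 ± 8.27 CPM (SD, n = 2 each). Its log2 change was 1.67 (SE 0.057, edgeR adjusted p = 0.00945). The next genes by p did not pass. These were Rnf121 (log2 change 0.99, edgeR adjusted p = 0.0536), Olig1 (1.65), the histone gene Hist1h2ap (1.31), Trib1, which encodes a COP1 partner (0.99), and the non-coding AW047730 (0.65), the last 4 each at an edgeR adjusted p of 0.101. Of 16973 genes tested, 1 rose and 0 fell by edgeR, 1787 had an unadjusted p under 0.05, and DESeq2 called 131 higher and 48 lower. Without HET replicate 1 or HET replicate 2 the count was 0 and Lgals1 was lost (edgeR adjusted p = 0.151 and 0.186), as it was with sex as a covariate, an alternative chosen after seeing the data (edgeR adjusted p = 0.0509). It was 146 without COP1 KO replicate 1 and 1210 without COP1 KO replicate 2.

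Genes of glial lineages were higher as groups in the whole-library sums. In the oligodendrocyte lineage list 12 of 14 members were higher, and adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 1.53e-05, adjusted p = 0.733 with an estimated correlation). Olig2 had a log2 change of 1.65 and Egfr, which encodes the epidermal growth factor receptor, of 1.44. In the astrocyte lineage list 14 of 17 were higher and 8 rose adjusted over the list alone (camera adjusted p = 9.09e-06, adjusted p = 0.733 with an estimated correlation). Gfap had a log2 change of 2.94, and the metallothionein genes Mt2 and Mt1 of 0.76 and 0.66. In the AP-1 and c-JUN target list 12 of 14 were higher. Of these Lgals1 rose over all genes and 5 rose adjusted over the list alone (camera adjusted p = 0.00307, adjusted p = 0.733 with an estimated correlation). That call was lost without COP1 KO replicate 2 (camera adjusted p = 0.351).

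The 7 transcription factors known as COP1 substrates were lower as a group at the RNA level. Of them 5 were lower and 4 fell adjusted over the list alone (camera adjusted p = 0.00473, adjusted p = 0.733 with an estimated correlation). The call was lost without COP1 KO replicate 2 (camera adjusted p = 0.0714). The log2 changes were −1.42 for Etv5, −1.37 for Etv4, −0.50 for Etv1 and −0.27 for Jun, with edgeR adjusted p over all genes of 0.101, 0.256, 0.298 and 0.292. Of the 11 measured members of the COP1 ligase complex and its partners, 2 rose adjusted over the list alone, the pseudokinase genes Trib1 and Trib2 (log2 change 0.32), while the group as a whole did not pass (camera adjusted p = 0.649). The ERK feedback and ETS target list had 3 members that rose and 3 that fell adjusted over the list alone (camera adjusted p = 0.834). The lists that were written knowing the study are no independent evidence for these directions.

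Markers of other cells and of RNA quality also moved with genotype. All 14 microglia and macrophage markers were higher (5 rose adjusted over the list alone, camera adjusted p = 9.09e-06, adjusted p = 0.733 with an estimated correlation), as with C1qb, a complement gene, at a log2 change of 0.54. Mitochondrially encoded genes were higher in 11 of 12 cases and 6 rose adjusted over the list alone (camera adjusted p = 0.00105, adjusted p = 0.733 with an estimated correlation), a call lost without HET replicate 2 (camera adjusted p = 0.0645). The median mitochondrial share of counts per cell was 1.14% and 1.13% in HET and 1.27% and 1.24% in COP1 KO. Hemoglobin genes held 0.25% and 0.11% of kept counts in HET and 0.30% in each COP1 KO library.

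Within classes, more genes differed in the radial-glia-like cells than in any other class tested, a ranking that did not hold without HET replicate 2, with 154 genes against 162 in intermediate-progenitor-like cells. Without COP1 KO replicate 2 the counts were 1087 and, in excitatory-neuron-like cells, 1085. Radial glia are the stem cells that line the ventricle of the embryonic cortex. In this class 248 genes rose and 103 fell in COP1 KO out of 11432 tested by edgeR. The largest rise was in Ndrg1, a differentiation- and stress-responsive gene (GRCm38.p6 chromosome 15, 66929318 to 66969641), from 11.1 ± 3.14 to 135.5 ± 11.7 CPM (SD, n = 2 each; log2 change 3.62, SE 0.189, edgeR adjusted p = 3.57e-05). Tm4sf1, which encodes a membrane protein, rose by 3.45 (SE 0.266, edgeR adjusted p = 0.000347) and Gfap by 3.18 on the log2 scale (SE 0.209, edgeR adjusted p = 0.000121), from 11.0 ± 1.06 to 99.6 ± 18.0 CPM (SD, n = 2 each). Among the genes that fell, Etv5 had a log2 change of −2.67 (SE 0.202, edgeR adjusted p = 0.00033), Etv4 of −2.31 (SE 0.295, edgeR adjusted p = 0.00363), and Lipg, a lipase gene, of −2.07 (SE 0.219, edgeR adjusted p = 0.00126). Scaling by library totals alone gave 215 that rose and 133 that fell. The count of 351 was 226 without HET replicate 1 and 476 without COP1 KO replicate 1. DESeq2 called 138 higher and 48 lower.

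**Figure D2:**
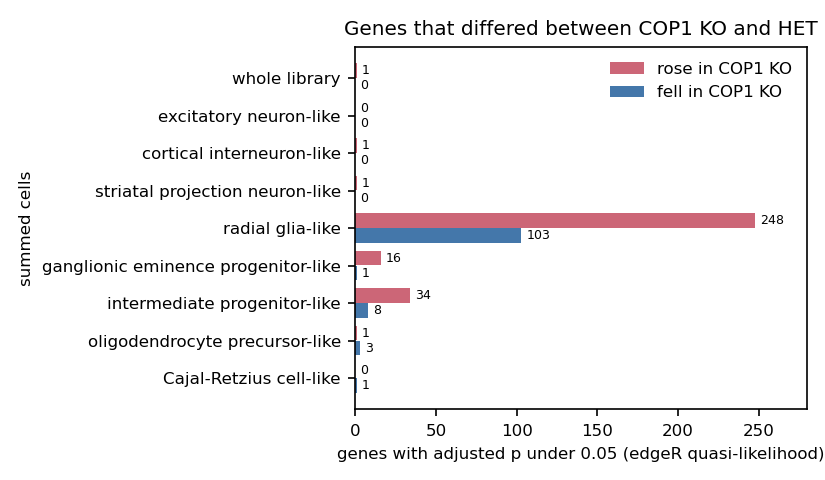
Number of genes (x axis) with an adjusted p under 0.05 by the edgeR quasi-likelihood test that rose or fell in COP1 KO, for whole-library sums and for sums over each class (y axis). Radial-glia-like cells have 248 genes that rose and 103 that fell, and every other bar is at most 34.

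The COP1 substrates were lower as a group in radial-glia-like cells. Of 5 measured, Jun, Etv4 and Etv5 fell (camera adjusted p = 0.0418, adjusted p = 0.805 with an estimated correlation, fry adjusted p = 0.0434). Jun, the gene of the AP-1 subunit c-JUN, went from 1565 ± 77.1 to 805.7 ± 99.6 CPM (SD, n = 2 each; log2 change −0.96, SE 0.095, edgeR adjusted p = 0.000864). Trib1 rose by 2.27 and Trib2 by 0.72 on the log2 scale (edgeR adjusted p = 7.15e-05 and 0.0203), 2 of the 10 measured partners (camera adjusted p = 0.698). AP-1 and c-JUN targets rose in 4 of 9 cases, and in 5 adjusted over the list alone (camera adjusted p = 0.00206, adjusted p = 0.805 with an estimated correlation, fry adjusted p = 0.0434). These 4 were Lgals1 (log2 change 2.96), Gfap, Anxa2, which encodes annexin A2 (1.64), and Vim (0.47), with edgeR adjusted p of 1.09e-05, 0.000121, 0.000421 and 0.00359. Of 12 ERK feedback and ETS targets, Ccnd1, the gene of cyclin D1, rose by 0.61 (edgeR adjusted p = 0.0222) and Etv4 and Etv5 fell (camera adjusted p = 0.943).

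**Figure D3:**
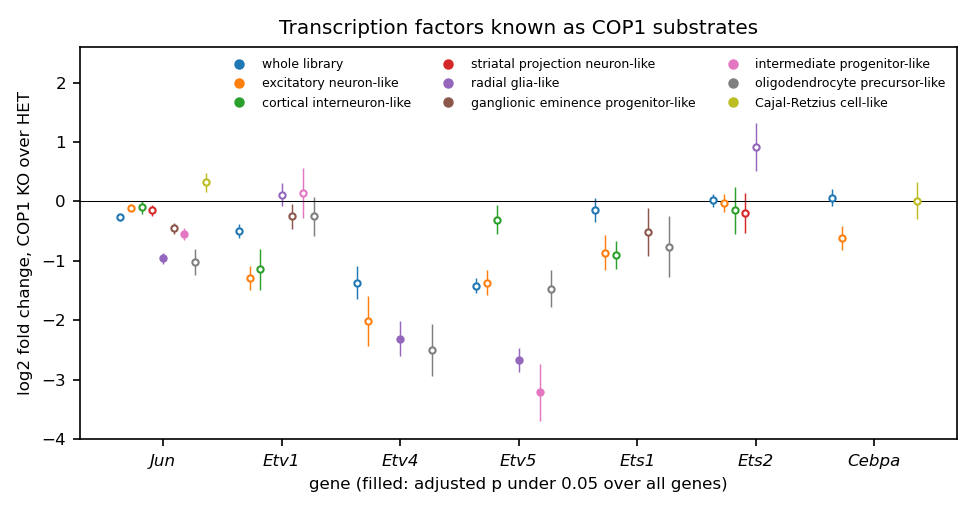
Log2 fold change of COP1 KO over HET (y axis) with its standard error (bars) for the transcription factors known as COP1 substrates (x axis), in whole-library sums and in each class where the gene was measured. Filled points passed the edgeR threshold over all genes: Jun, Etv4 and Etv5 in radial-glia-like cells and Jun and Etv5 in intermediate-progenitor-like cells, where both were lost with DESeq2 (adjusted p = 0.242 and 0.0989).

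Glial genes rose in the same cells. In the astrocyte lineage list 7 of 17 rose and 1 fell, and 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000239, adjusted p = 0.805 with an estimated correlation, fry adjusted p = 0.0434). Aldh1l1, a folate enzyme gene of astrocytes, rose by 1.21 and Sparcl1, which encodes a secreted matrix protein, by 1.51 on the log2 scale (edgeR adjusted p = 0.000439 and 0.000653). In the oligodendrocyte lineage list Olig1 (log2 change 1.96) and Olig2 (1.65) rose out of 8 measured, with edgeR adjusted p of 0.00848 and 0.00503, and 4 rose adjusted over the list alone (camera adjusted p = 0.0256, adjusted p = 0.805 with an estimated correlation). Olig1 was lost in cluster 12 alone (edgeR adjusted p = 0.0789), an alternative chosen after seeing the data. The 2 genes were higher by as much in excitatory-neuron-like cells (log2 changes 1.97 and 2.03, neither past the edgeR threshold), at means of only 2.18 and 1.03 CPM in COP1 KO, and the test of a difference between the classes was not passed (log2 differences −0.007 and −0.36). Markers of other cells were higher there too, though neither list passed. Blood markers were higher in 3 of 3 cases (median log2 change 2.84), and 3 rose adjusted over the list alone (camera adjusted p = 0.172). Vessel and meninges markers were higher in 3 of 4 cases (median 1.47), and 1 rose over all genes (camera adjusted p = 0.102). The radial glia list itself was mixed, with Vim and Dbi rising and 4 of 15 falling (camera adjusted p = 0.696). Those that fell were Gas1 (log2 change −0.61), the Notch effector Hes1 (−0.58), the lipid-binding gene Fabp7 (−0.38) and the transcription factor gene Pax6 (−0.71), with edgeR adjusted p of 0.00359, 0.00871, 0.00747 and 0.0125.

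Genes of neurogenic commitment and of the G2 and M phases were lower as groups. Of 10 intermediate progenitor genes, Neurog2 (log2 change −0.64, edgeR adjusted p = 0.00285) and Neurog1 (−2.38, edgeR adjusted p = 0.0496) fell, both proneural transcription factors (camera adjusted p = 0.00946, adjusted p = 0.805 with an estimated correlation). Neurog2 was lost in cluster 16 alone (edgeR adjusted p = 0.246). Of 51 G2 and M phase genes 48 were lower, of which Hmgb2 (−0.74), a chromatin protein gene, and Cks2 (−0.45), a cyclin kinase subunit gene, fell, and 4 fell adjusted over the list alone (camera adjusted p = 1.69e-05, adjusted p = 0.805 with an estimated correlation). S phase genes were lower in 29 of 40 cases, 0 fell, and the list did not pass (camera adjusted p = 0.127). All 15 cholesterol synthesis genes were lower, 1 fell over all genes, Stard4 (−0.68, edgeR adjusted p = 0.0444), and 7 fell adjusted over the list alone (camera adjusted p = 0.000162, adjusted p = 0.805 with an estimated correlation). The mitochondrially encoded genes were higher in 10 of 10 cases, and 6 rose adjusted over the list alone (camera adjusted p = 0.00179, adjusted p = 0.805 with an estimated correlation). Cells with 2 or more of 6 cycling genes, thinned, were 46.9% ± 1.92 of HET and 40.2% ± 1.44 of COP1 KO radial-glia-like cells (SD, n = 2 each; 59.9% and 50.3% unthinned). In intermediate-progenitor-like cells they were 30.8% ± 4.26 and 36.4% ± 4.02 (SD, n = 2 each; 38.2% and 41.5% unthinned), with overlapping libraries. Over all cells they were 7.59% and 9.15% (9.68% and 11.3% unthinned), against 0.189% and 0.185% in excitatory-neuron-like cells.

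**Figure D4:**
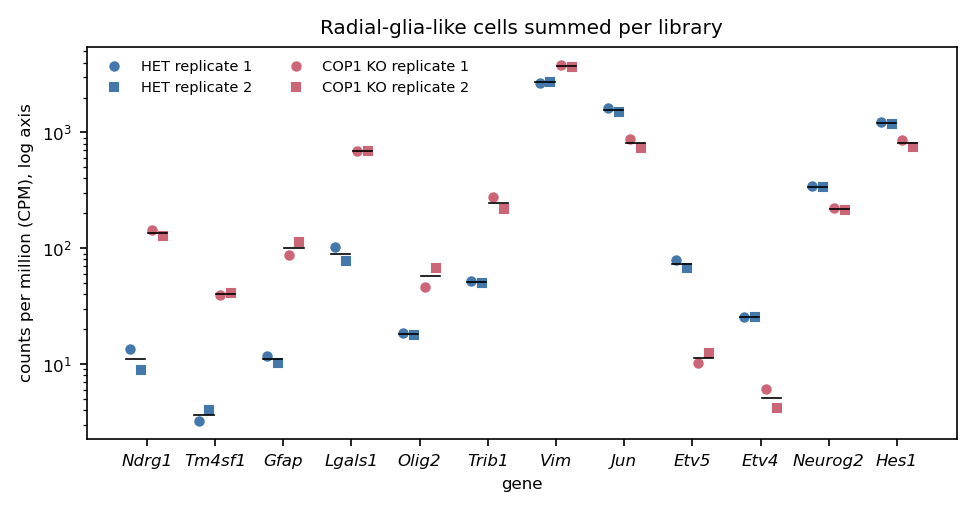
CPM (y axis, log scale) of 12 genes in radial-glia-like cells summed per library, with points for libraries and lines for genotype means. Etv5 lies at 78.6 and 67.3 CPM in HET and 10.2 and 12.5 CPM in COP1 KO, and Gfap at 11.8 and 10.3 CPM in HET and 86.9 and 112.3 CPM in COP1 KO.

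Intermediate-progenitor-like cells, which stand between radial glia and neurons, had fewer genes past the threshold. In them 34 genes rose and 8 fell of 9722 tested by edgeR. Lgals1 rose by 2.77 (SE 0.21, edgeR adjusted p = 6.32e-05), Tagln2, an actin-binding gene, by 3.13 (SE 0.441, edgeR adjusted p = 0.00985), the imprinted non-coding H19 by 2.84 (SE 0.35, edgeR adjusted p = 0.00484) and Col25a1, a collagen gene, by 3.29 on the log2 scale (SE 0.566, edgeR adjusted p = 0.0233). Etv5 had a log2 change of −3.21 (SE 0.485, edgeR adjusted p = 0.00985) and Jun of −0.55 (edgeR adjusted p = 0.0349), and both fell, 2 of 3 measured substrates (camera adjusted p = 0.0198, adjusted p = 0.805 with an estimated correlation). With DESeq2, Etv5 (adjusted p = 0.0989), Jun (0.242), Col25a1 (0.104) and Chga (0.192) were lost. With edgeR, doublets kept lost Jun (adjusted p = 0.0645) and Col25a1 (0.0819), and Jun was also lost at 1000 genes or more (0.0863) and without the top doublet scores (0.0976). Enc1, an actin-associated gene of neurons, and Chga, which encodes chromogranin A, fell (log2 change −0.88 and −1.06, edgeR adjusted p = 0.00985 and 0.0215). AP-1 targets were higher as a group (camera adjusted p = 0.000154), as were the oligodendrocyte (0.000825), astrocyte (0.00145) and mitochondrially encoded (0.00154) lists, each at an adjusted p = 0.805 with an estimated correlation. Of the mitochondrially encoded genes 9 of 9 were higher and 6 rose adjusted over the list alone. The unadjusted p was under 0.05 for 1042 genes, and DESeq2 called 17 higher and 1 lower. With sex as a covariate, an alternative chosen after seeing the data, 163 rose and 66 fell. Without HET replicate 1, HET replicate 2, COP1 KO replicate 1 or COP1 KO replicate 2 the count of 42 became 113, 162, 113 or 387.

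In ganglionic-eminence-progenitor-like cells, progenitors of inhibitory neurons, 16 genes rose and 1 fell of 9190 tested by edgeR. Lgals1 rose by 2.27 (SE 0.109, edgeR adjusted p = 5.34e-07) and Slc1a3, a glial glutamate transporter gene, by 1.72 on the log2 scale (edgeR adjusted p = 7.8e-05). Apold1 (2.98), Nxph1 (2.59), which encodes a neurexin ligand, and Serpine2 (2.34), a protease inhibitor gene, rose with edgeR adjusted p of 0.0118, 0.0163 and 0.0214. For Apold1, 3 cells held 27 of 37 counts in COP1 KO replicate 1 and 52 of 68 in COP1 KO replicate 2. Nxph1 and Serpine2 were lost with DESeq2 (adjusted p = 0.0991 and 0.586). Mitochondrially encoded genes were higher in 9 of 9 cases and 6 rose adjusted over the list alone (camera adjusted p = 0.000814, adjusted p = 0.805 with an estimated correlation). Hemoglobin genes were among those that rose, and without cells rich in hemoglobin or Ttr, an alternative chosen after seeing the data, 7 rose and 0 fell. The unadjusted p was under 0.05 for 712 genes, and DESeq2 called 9 higher and 0 lower. Nxph1 was lost without HET replicate 1 or HET replicate 2 (edgeR adjusted p = 0.0612 and 0.0517). The count of 17 was 10 without HET replicate 1, 78 without COP1 KO replicate 1 and 287 without COP1 KO replicate 2.

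In oligodendrocyte-precursor-like cells 1 gene rose and 3 fell of 8057 tested by edgeR. Lgals1 rose by 2.07 on the log2 scale (SE 0.211, edgeR adjusted p = 0.0258), but its HET level rests on few cells, with 87 of 93 and 83 of 134 counts in 3 cells of each library. Scrg1 (−1.91), Ostf1 (−2.32) and Car8 (−2.79), a carbonic anhydrase-related gene, fell, each at an edgeR adjusted p of 0.0444. With sex as a covariate, an alternative chosen after seeing the data, all 4 were lost, each at an edgeR adjusted p of 0.116. The COP1 substrates were lower in 5 of 5 cases and 3 fell adjusted over the list alone (camera adjusted p = 0.00058, adjusted p = 0.805 with an estimated correlation, fry adjusted p = 0.0434). The G2 and M phase genes were higher in 48 of 51 cases and 26 rose adjusted over the list alone (camera adjusted p = 5.56e-18, adjusted p = 0.805 with an estimated correlation). The oligodendrocyte lineage list was lower in 11 of 14 cases and 4 fell adjusted over the list alone (camera adjusted p = 0.00915, adjusted p = 0.805 with an estimated correlation). The astrocyte lineage list was lower in 11 of 15 cases (camera adjusted p = 0.0089) and the immediate early and dissociation stress genes in 12 of 15 (camera adjusted p = 0.00601), both at an adjusted p = 0.805 with an estimated correlation. Choroid plexus markers were lower in 6 of 6 cases (median log2 change −2.69) and did not pass as a list (camera adjusted p = 0.179). The count of 4 was 2 without HET replicate 1, where Scrg1 and Ostf1 were lost (edgeR adjusted p = 0.115 each), 129 without HET replicate 2, 63 without COP1 KO replicate 1 and 133 without COP1 KO replicate 2. With all libraries, the unadjusted p was under 0.05 for 734 genes, and DESeq2 called 3 higher and 14 lower. HET sums here rest on 34 and 36 cells. Of these, 4 in HET replicate 1 and 0 in HET replicate 2 held 100 or more counts of Ttr, a choroid plexus marker. In COP1 KO, 0 of 115 and 3 of 140 cells did, so such cells were spread unevenly. Without cells rich in Ttr or hemoglobin, an alternative chosen after seeing the data, 4 genes rose and 13 fell.

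Among postmitotic cells few genes differed. In excitatory-neuron-like sums 0 of 14662 genes passed the edgeR test, 1347 had an unadjusted p under 0.05, and DESeq2 called 39 higher and 25 lower. The substrates were lower in 7 of 7 cases and 5 fell adjusted over the list alone (camera adjusted p = 3.94e-05, adjusted p = 0.805 with an estimated correlation, fry adjusted p = 0.0434). Etv1 had a log2 change of −1.29 and Etv5 of −1.37. The oligodendrocyte lineage list was higher in 7 of 8 cases (camera adjusted p = 0.00175) and the mitochondrially encoded list in 10 of 12 (camera adjusted p = 0.00485), both at an adjusted p = 0.805 with an estimated correlation. Rnf121, which encodes a RING finger protein, rose in interneuron-like cells (log2 change 1.30, SE 0.105, edgeR adjusted p = 0.0135) and in striatal-projection-neuron-like cells (1.43, SE 0.127, edgeR adjusted p = 0.00273), the 1 gene that rose in each, with 0 that fell. In interneuron-like sums 714 genes had an unadjusted p under 0.05 and DESeq2 called 1 higher and 1 lower, while in striatal sums 640 had an unadjusted p under 0.05 and DESeq2 called 2 higher and 0 lower. With sex as a covariate, an alternative chosen after seeing the data, 33 rose and 14 fell in striatal sums. Rnf121 in interneuron-like cells was lost without HET replicate 1 (edgeR adjusted p = 0.109) or HET replicate 2 (edgeR adjusted p = 0.0682). In Cajal-Retzius-like cells Penk, the proenkephalin gene, fell from 64.7 ± 14.3 to 4.58 ± 0.769 CPM (SD, n = 2 each; log2 change −3.76, edgeR adjusted p = 0.0125). It rests on 12 of 122 HET cells and 4 of 125 COP1 KO cells, with 24 of 27 and 27 of 36 counts of the HET libraries in 3 cells each, and was lost without HET replicate 2 (edgeR adjusted p = 0.0875) and with DESeq2 (adjusted p = 0.254). Of 7393 genes there, 0 rose and 1 fell by edgeR, 464 had an unadjusted p under 0.05 and DESeq2 called 0. Without HET replicate 1, HET replicate 2, COP1 KO replicate 1 or COP1 KO replicate 2 the counts were 0, 0, 102 and 1085 for excitatory-neuron-like cells and 0, 0, 27 and 282 for interneuron-like cells. They were 8, 11, 60 and 372 for striatal-projection-neuron-like cells and 3, 1, 11 and 118 for Cajal-Retzius-like cells.

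The difference between progenitors and neurons was tested directly. The genotype effect differed between radial-glia-like and excitatory-neuron-like cells for 406 of 14944 genes by edgeR, 262 of them more positive and 144 more negative in radial-glia-like cells. Of the 351 genes that differed in radial-glia-like cells, 213 passed this test. Ndrg1 had a difference of 3.49 (SE 0.177, edgeR adjusted p = 4.09e-30), Lgals1 of 1.94 (SE 0.169, edgeR adjusted p = 3.92e-16), Trib1 of 2.08 (SE 0.154, edgeR adjusted p = 1.75e-19) and Jun of −0.85 on the log2 scale (SE 0.069, edgeR adjusted p = 1.94e-17). Olig1, at −0.01, and Etv4, at −0.31 (SE 0.789), did not pass. Olig1 was scarce in excitatory-neuron-like cells, so equal effects in these classes are not shown. Without HET replicate 1 the count was 162, without HET replicate 2 it was 165, and without COP1 KO replicate 1 it was 269.

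**Figure D5:**
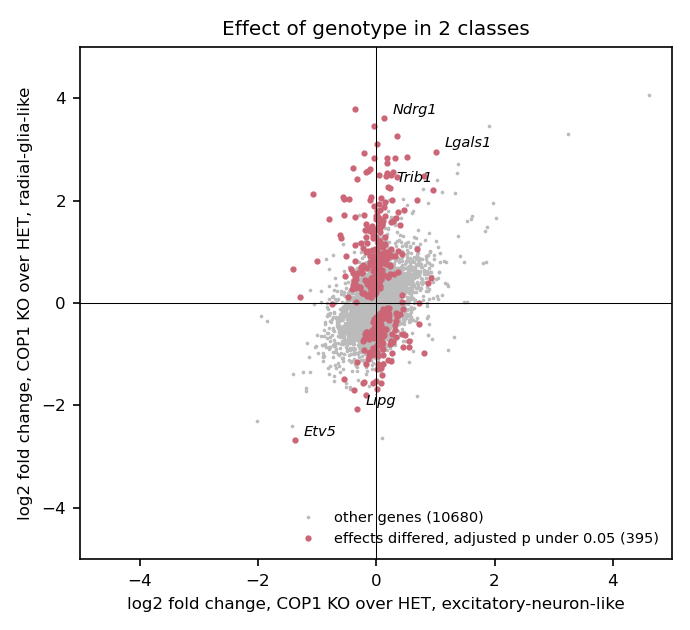
Log2 fold change of COP1 KO over HET in excitatory-neuron-like (x axis) against radial-glia-like cells (y axis) for 11075 genes measured in both (points). The 395 plotted genes whose effects differed by the edgeR test spread along the y axis, with Ndrg1 at 3.62 in radial-glia-like and 0.14 in excitatory-neuron-like cells.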

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

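The test of a difference between radial-glia-like and excitatory-neuron-like cells was planned, and the tests of explanations for the 2 patterns below were chosen only after the results were seen. The genotype effect differed between these classes for 262 genes that were more positive and 144 that were more negative in radial-glia-like cells. Among genes named for radial-glia-like cells, those that passed included, with a positive difference in log2 change, Ndrg1 (3.49), Trib1 (2.08), Lgals1 (1.94), Sparcl1 (1.59) and Vim (0.45). With a negative difference they included Lipg (−1.74), Etv5 (−1.30), Jun (−0.85), Neurog2 (−0.74) and Hmgb2 (−0.50). Others named there did not pass: Tm4sf1 (1.64), Gfap (0.42), Aldh1l1 (0.21), Dbi (0.14), Anxa2 (0.042), Olig1 (−0.007), Fabp7 (−0.18), Etv4 (−0.31), Olig2 (−0.36) and Hes1 (−0.60) among them.

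The 351 genes that differed in radial-glia-like cells could come from a shift between clusters 12 and 16, the latter of dividing cells. However, all 339 of them tested in cluster 12 alone and all 329 tested in cluster 16 alone changed in the same direction. Of these, 178 and 202 also passed there. The agreement in direction is partly built in, because the genes were picked from the sums of these same clusters. COP1 KO replicate 1, which stood apart, is not the whole source, since 320 of the 351 also passed without it. Cells of the oligodendrocyte-precursor-like class within the radial-glia-like class are not the main source: thinned shares of Olig1, Olig2, Sox10 and Pdgfra allow at most 5.5%, 15.3%, 0% and 0.8% of such cells in COP1 KO, and 15.3% would bring a median of 12.8% of the log2 change (upper quartile 25.3%). For 25 of the 351 genes it would bring 50% or more, so a contribution to these stays open. By direction alone, 237 of the 351 genes changed toward the level of the precursor-like class in HET. These were 151 of the 248 that rose and 86 of the 103 that fell. Both directions were taken from the same HET radial-glia-like sums, so noise in those sums favours agreement. The share over all tested genes was not computed, so this count decides nothing. The genotype itself is a candidate cause as well, and differences between these mice other than genotype were not tested.

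The higher share of oligodendrocyte-precursor-like cells was not set by cluster boundaries alone, since the log2 ratio was 1.54 (SE 0.233) when the called genes were left out of the clustering. Fewer excitatory neurons recovered would raise all the remaining classes alike, but the median log2 ratio of the other 11 named classes, excitatory neurons aside, was 0.096 (SD 0.263), and a lower recovery of all other types together was not tested. Whether progenitors joined the class through Olig1 and Olig2 without other precursor genes cannot be told from the share over all cells. Thinned cells with 2 or more of 7 other precursor genes were 0.384% of HET and 0.592% of COP1 KO cells, a ratio of 1.541 (SD 0.889) with overlapping libraries, against 2.19 (SD 0.66) unthinned, where the libraries lay apart, and 1.03 (SD 0.19) at 1000 counts. Within the class, cells with 2 or more of these genes were 45.7% of HET and 20.8% of COP1 KO cells thinned. They were 30.1% and 9.43% at 1000 counts and 61.2% and 48.2% unthinned, with libraries apart each time. A smaller part of the class thus held these genes in COP1 KO, which goes with such joining. Lower levels of these genes in precursors would give it too. The genotype may have changed the number of precursor-like cells, their gene expression or both.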

How the results depend on the processing

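The named genes that were run, other than Cop1, kept their direction in all 1127 gene and setting combinations. Many had been picked for their change in these same counts, so a kept direction was largely built in. Some genes named above were not run, among them Trib2, Ccnd1, Gas1 and Pax6. The side of the threshold was the same in 1003, 27 no longer passed and 97 newly passed. No paired analysis was possible because the labels give no replicate numbers that pair the mice, apart from a pairing by sex, which was read from the counts. With 1 female and 1 male mouse of each genotype, sex as a covariate is a fit of 2 pairs. Sex as a covariate, the top 4% of doublet scores, cells rich in Ttr or hemoglobin, the radial-glia-like clusters taken singly and the interaction with a library left out were alternatives chosen after seeing the data. For the moved values below the cause was not tested unless it is given.

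Counts of genes that differed moved by over 1.5 times as follows. DESeq2 called 179 genes in the whole library, 64 in excitatory-neuron-like, 2 in interneuron-like, 2 in striatal, 186 in radial-glia-like, 9 in ganglionic-eminence-progenitor-like, 18 in intermediate-progenitor-like, 17 in oligodendrocyte-precursor-like and 0 in Cajal-Retzius-like cells. Without a filter on low counts the counts in the same classes were 13, 208, 153, 827, 145, 225, 301 and 28. With sex as a covariate they were 0 for the whole library, 2 interneuron-like, 47 striatal, 27 ganglionic-eminence-progenitor-like, 229 intermediate-progenitor-like and 0 oligodendrocyte-precursor-like. Library totals gave 2 for the whole library and 7 for oligodendrocyte-precursor-like cells, and thinning to equal totals gave 2 for the whole library. Oligodendrocyte-precursor-like cells had 9 with size factors, 10 with doublets kept, 8 at 1000 genes or more, 34 without the top doublet scores and 17 without rich cells. Ganglionic-eminence-progenitor-like cells had 7 without rich cells, and intermediate-progenitor-like cells had 75 at resolution 2.0. Cluster 12 alone gave 195 and cluster 16 alone 231 in radial-glia-like cells, which hold fewer cells each.

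Leaving out each library in turn gave 0 to 1210 genes in the whole library, 0 to 1085 in excitatory-neuron-like, 0 to 282 in interneuron-like, 8 to 372 in striatal, 154 to 1087 in radial-glia-like, 10 to 287 in ganglionic-eminence-progenitor-like, 113 to 387 in intermediate-progenitor-like, 2 to 133 in oligodendrocyte-precursor-like and 1 to 118 in Cajal-Retzius-like cells. The interaction gave 162 to 309. Counts were highest without COP1 KO replicate 2, where the lone COP1 KO library is the one that stood apart, and its differences count as genotype. The oligodendrocyte-precursor-like share kept a log2 ratio of 1.48 to 1.90 and missed the threshold at 1.63 without HET replicate 1 and 1.78 without HET replicate 2. Of the 11 lists called in the whole library (6 to 14 with each library left out), 0 held with an estimated correlation and 0 with fry, and of the 36 within classes 0 and 6.

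Among shares, Cop1, the named genes that were run and called lists, the values that changed sign were log2 ratios of shares and 1 log2 change of Cop1. For unnamed cells they were −0.20 at resolution 0.5, −0.018 at 2.0, −0.06 with doublets kept, −0.10 at 1000 genes or more, −0.11 without the top doublet scores, −0.039 with TMM and −0.18 when clustered without the called genes, where erythroid-like cells were at −0.15. For endothelial-like cells they were −0.002 with TMM and −0.088 without rich cells. With each library left out in turn, the log2 ratio crossed 0 for unnamed (−0.13 to 0.18), endothelial-like (−0.77 to 0.55), excitatory-neuron-like (−0.078 to 0.013), intermediate-progenitor-like (−0.27 to 0.034), mural-like (−0.061 to 0.32) and striatal-projection-neuron-like cells (−0.16 to 0.063). The log2 change of Cop1 in excitatory-neuron-like cells ranged likewise from −0.29 to 0.014. Some lists not called in the whole library changed direction too. The median log2 change of choroid plexus markers was 1.67 without HET replicate 1 and −1.29 without HET replicate 2. No ratio could be computed for erythroid-like cells without rich cells. The thinned ratio of 1.31 for Vim was 1.17 unthinned, and the cycling ratio of 0.856 in radial-glia-like cells was 0.772 at 1000 counts and 0.776 with 3 or more genes. Depth limits classes of few cells most: oligodendrocyte-precursor-like sums held as few as 276716 counts, so differences in genes of low expression may be missed there. The spread between libraries was also larger, with a biological coefficient of variation of 18.9% against 9.9% in radial-glia-like cells. Recovery of changed genes was not simulated for this class.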

Other observations

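All tests in this part were chosen after the data were seen, apart from the thinned shares and list tests, which were planned. Shares of cells with a molecule of some genes were also compared within the oligodendrocyte-precursor-like class. Pdgfra was found in 40.0% ± 1.62 of HET and 21.3% ± 6.29 of COP1 KO cells of this class after thinning (SD, n = 2 each; 51.5% and 40.8% unthinned), and Sox10 in 27.0% ± 4.97 and 14.1% ± 2.35 (42.8% and 28.9% unthinned). Olig1 was in 80.1% ± 7.28 and 80.2% ± 5.40, and Olig2 in 59.9% ± 5.66 and 57.9% ± 3.16. Vim was in 84.3% ± 1.39 and 98.0% ± 0.264 (92.9% and 99.6% unthinned). Gfap was in 0% and 2.76% ± 0.143 (2.86% and 5.47% unthinned), but in 1.39% and 1.15% at 1000 counts. Cells with 2 or more cycling genes were 19.9% ± 7.28 of the HET and 41.6% ± 1.25 of the COP1 KO cells of this class (35.6% and 54.3% unthinned). In the sums of this class Ube2c, a gene of the ligase machinery that ends mitosis, had a log2 change of 1.30 and Pdgfra of −1.13, with edgeR adjusted p of 0.0687 and 0.197, so neither passed. These shares rest on 70 HET and 255 COP1 KO cells, and no test beyond the edgeR test of the genes was made.

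Across all cells, S phase genes were higher in 36 of 40 cases in the whole-library sums (camera adjusted p = 0.000309) and G2 and M phase genes in 39 of 51 (camera adjusted p = 0.00279), each with 0 past the edgeR threshold. The adjusted p = 0.733 with an estimated correlation for both. The S phase call was lost without COP1 KO replicate 1 (camera adjusted p = 0.173), and the G2 and M phase call without HET replicate 1 (0.528) or COP1 KO replicate 2 (0.138). Cholesterol synthesis genes were lower in 15 of 15 cases there (camera adjusted p = 0.00244, adjusted p = 0.733 with an estimated correlation). A small unnamed cluster, led by Tesc, Rspo1, Wnt8b and Gfap, held 14 and 13 HET cells and 31 and 23 COP1 KO cells.

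COP1 KO replicate 1 differed from the other libraries in 324 genes outside the sex-linked ones by over 0.5 log2 units, among them AA465934 (5.16), Nptn (−2.51) and Lrrn1 (−2.33), all chosen after their values were seen. For the 273 of these genes with a mean over 20 CPM in excitatory-neuron-like cells, a different mix of cell types is not the main source. Within those cells a median of 102.1% of their deviation was kept. The rest of the 324 were below that level there and were not compared, so for them a different mix stays open. It may also be the source for single genes among the 273. Ttr deviated by −2.90 in the whole library but by −0.31 in excitatory-neuron-like and −0.77 in radial-glia-like cells. GC content of the last 500 bases and transcript length explained 6.4% of the variance of the deviation over the 310 of these genes with a transcript sequence, so they are not the main source. A difference between library preparations, or between these mice, may be the cause, and the labels give no batch to test it.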
